A study of Mus musculus with 21 samples.

How the data were processed

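RNA from 15 liver tumours of mice given the vector LV.ET.LTR at birth and from 6 non-tumoral livers had been labelled with biotin and hybridised to 1-colour Affymetrix whole-transcript arrays, per the labels' protocols. The deposited values are normalized probe intensities, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions and a genome build are not given in the sources used here. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a set, so differences in total RNA between samples cannot be seen in these values, and changes of weak genes are compressed. The table held 28837 probe rows and 21 arrays. The tests had been planned for values on the log2 scale, but the deposited intensities were on a linear scale, so log2 was taken before every test. Array medians of the log2 values lay between 5.57 and 5.76.

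Probes were named from the platform annotation. Of the rows, 21780 had exactly 1 gene symbol, 1605 had several and 5452 were not listed in that annotation; the latter 2 kinds were left unnamed and kept out of the tests. Of the probes with 1 symbol, 21689 matched a gene ID in the RefSeq name table (assembly GRCm38.p6), and 0 symbols were updated. That table served for names only, and no coordinates are given because the build behind the values is unknown. Each of 19935 genes was represented by its probe with the highest mean over all arrays, and 998 genes had more than 1 probe. Named genes whose probes disagreed are pointed out beside their values. No filter on dim genes was applied. Arrays are described by group and by the name in their titles, which starts with N for a liver and T for a tumour. No 2 arrays were duplicates: the highest Pearson correlation across genes between any pair was 0.9898 and at most 119 probe values were identical.

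Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 19935 genes and a threshold of 0.05. The overall tumour-liver comparison used all 21 arrays with mouse line and CCl4 status as an additive term. The comparisons between groups used a mean per group over all 21 arrays, which share an estimate of the spread. The comparisons by marking gene used the 10 wild type CCl4 tumours. The 4 insertion-site genes were compared by exact two-sided permutation tests of the difference in mean log2 value, adjusted over the 4 genes, or over the 3 testable within the wild type CCl4 tumours. Values with ± are log2 means with SD, or log2 differences with SE. The comparisons, their tests and alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

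That rule named the 12 genes with the largest rise and the 12 with the largest fall in each of the first 3 comparisons, and 8 each way in the others. They had to pass the threshold with a mean log2 value of at least 6 in the higher group, and predicted genes, microRNAs, small nucleolar RNAs and olfactory receptors were left out. The targeted genes, the insertion-site genes, up to 4 members of each list by smallest p, and the imprinted neighbours of Rtl1 were named as well. In total 34 gene lists from textbook knowledge, of pathways, liver zones and cell types, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 34 lists within each comparison; 449 of 494 list entries were measured. For each list the genes past the threshold over all genes are given beside those adjusted over the list alone. For the pair of arrays without replicates, list medians were set against 10000 random lists matched on expression.

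Each gene test was run on simulated data with 200 changed genes, the real gene means and the real residual spread, over 19935 genes. For the knockout tumour-liver comparison 61% of 2-fold and 92% of 4-fold changes were recovered. For the wild type CCl4 comparison, with 2 livers, these were 68% and 89%, and for the Rtl1 comparison 69% and 95%. The simulated genes were independent and had the same spread in every group, so these shares do not speak for correlated genes or unequal spreads. The alternatives were leaving out the 30% of genes with the lowest means, centring arrays, an intensity trend with robust variance, array weights, the title number as a replicate block, the mean of a gene's probes, only the arrays compared, a fold threshold and leaving out each array in turn. After seeing the data, the Xist level as a covariate, the title number as a fixed block in the Rtl1 comparison, subsets of the wild type tumours by Rtl1 mark, and fits without knockout tumours T31 and T74 were added.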

Results

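Gene expression was measured in 15 mouse liver tumours and 6 samples of non-tumoral liver, each on a single Affymetrix whole-transcript array hybridised with biotin-labelled material made from total RNA. Newborn mice had received LV.ET.LTR, a lentiviral vector used as an insertional mutagen, in which integration next to a gene can alter that gene's expression. The livers are labelled as coming from control mice, and whether those mice had received the vector is not settled by the labels. The labels name, for each tumour, the gene or genes at a recurrent integration site retrieved from it (Braf, Fign, Rtl1 or Sos1). A tumour whose label names a gene is called marked by that gene below. The mice were either wild type or lacked both Cdkn2a, which encodes the p16 and Arf tumour suppressors, and Ifnar1, a subunit of the type I interferon receptor (called knockout below). Some wild type mice had also been given CCl4, a hepatotoxin that injures pericentral hepatocytes. The groups were 4 knockout tumours and 3 knockout livers without CCl4, 10 wild type tumours and 2 wild type livers with CCl4, and 1 wild type tumour and 1 wild type liver without CCl4. The 2 mouse lines also differed in strain make-up, so genotype, strain and CCl4 changed together between the knockout groups and the wild type groups given CCl4. The labels do not tie arrays to animals. 5 of the wild type tumours, TA161 to TE161, share the number in their titles, and so do TA159 and TB159. Each knockout tumour shares its number with a knockout liver (N31, N74 or N102), and T102B also with another knockout tumour. The wild type tumour and liver without CCl4 share a number as well. The main tests did not pair same-numbered arrays, so p-values measure the spread between arrays, some of which may share an animal. Median log2 intensity over all probes lay between 5.57 and 5.76 on every array, and the number of arrays limits the precision of every value below.

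The targeted genes were examined first. Ifnar1 was lower in the knockout tumours (log2 7.02 ± 0.23, SD, n = 4) than in the wild type CCl4 tumours (8.53 ± 0.18, n = 10), a difference of -1.51 ± 0.16 (SE; limma adjusted p = 4e-06). In the livers Ifnar1 stood at 7.04 ± 0.58 (n = 3) and 8.22 ± 0.03 (n = 2), with an adjusted p of 0.185. Cdkn2a was low everywhere, at 5.82 ± 0.16 in knockout tumours and 5.63 ± 0.17 in wild type CCl4 tumours (adjusted p = 0.237). Where these probes lie relative to the deleted parts was not established, so a similar signal checks nothing about the labels.

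Each of the 4 insertion-site genes was higher in the tumours marked by it than in the other tumours. Rtl1, a retrotransposon-derived gene of the imprinted Dlk1-Dio3 cluster, averaged 11.04 ± 0.52 (SD, n = 7) in marked and 6.78 ± 1.13 (n = 8) in other tumours. That is a 19.2-fold difference (exact two-sided permutation p = 0.000155, adjusted p = 0.00062), and all 7 marked tumours lay above all others. The unmarked tumours ranged from 5.25 to 8.69, and of them only T31 (5.47) and TB159 (5.25) lay within the range of the livers (4.92 to 6.12). Fign, which encodes a microtubule-severing ATPase, was 12.4-fold higher in 4 marked tumours than in 11 others (exact permutation p = 0.000733, adjusted p = 0.00147). Braf, a kinase of the ERK cascade, was 3.13-fold higher in 3 marked tumours than in 12 others (exact permutation p = 0.0022, adjusted p = 0.00293). For these 3 genes the p is the smallest that the design allows. Sos1, a guanine nucleotide exchange factor for Ras, was 3.02-fold higher (exact permutation p = 0.0154, adjusted p = 0.0154; 3 marked tumours, 12 others). The Sos1 difference rested on tumours TB159 (10.05) and TE161 (9.62), because TD161, labelled with Rtl1 and Sos1, stood at 7.62, within the range of the livers (7.15 to 7.88). The adjusted p became 0.0769 without TB159 and 0.0769 without TE161. Within the 10 wild type CCl4 tumours, the differences were 4.12 for Rtl1 (exact permutation p = 0.00476), 3.42 for Fign (p = 0.00833) and 1.42 for Sos1 (p = 0.05), with adjusted p of 0.0125, 0.0125 and 0.05, so Sos1 did not pass there. All 3 Braf-marked tumours were knockout, so Braf could not be compared within the wild type tumours.

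**Figure D1:**
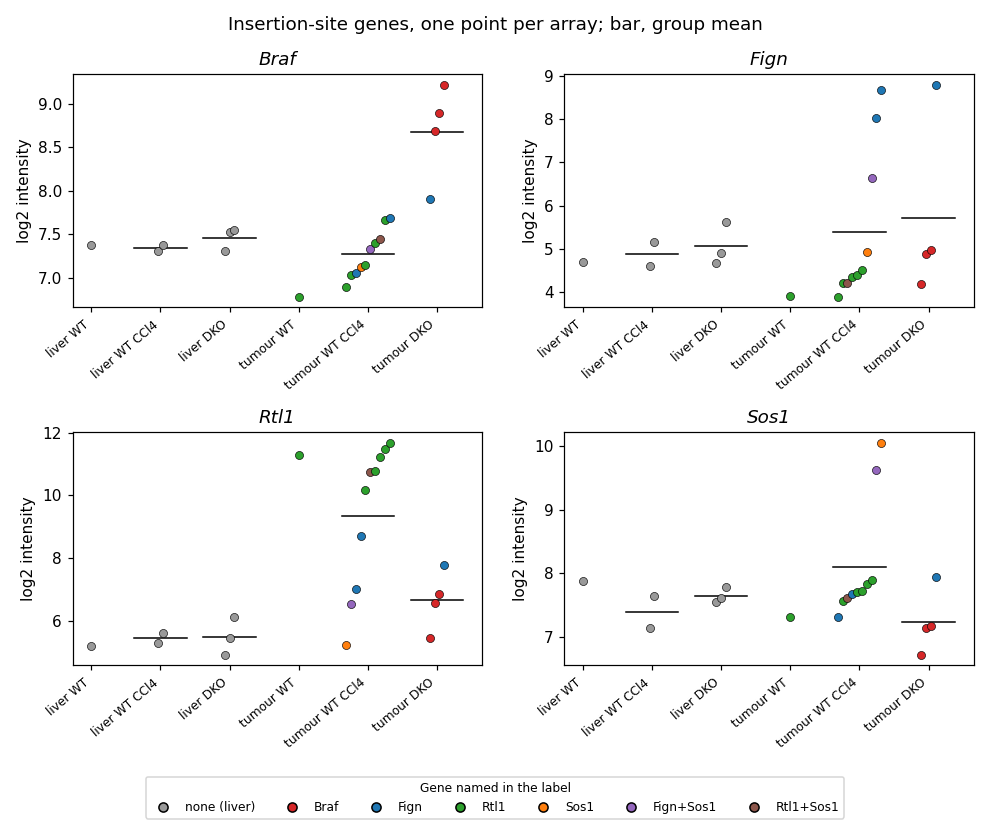
Log2 intensity of Braf, Fign, Rtl1 and Sos1 on each array (y axis) by group (x axis), coloured by the gene named in the label; bars are group means. Rtl1 lies between 10.18 and 11.67 in the 7 marked tumours and between 4.92 and 6.12 in the 6 livers.

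In a principal component analysis of all 19935 genes, the first component (30.2% of the variance) set the 4 knockout tumours, at -78.68 to -58.57, apart from the other arrays. The second (20.4%) set the 7 Rtl1-marked tumours, at -48.92 to -30.09, apart from the rest. The 4 wild type CCl4 tumours without the Rtl1 mark lay between 10.79 and 22.13 on the second component, and the 6 livers between 18.65 and 31.25. Knockout liver N31 lay at -8.25 on the first component, while the other livers lay at 23.93 or above. Its Mki67, a proliferation marker, was 8.79, against 5.45 to 6.16 in the other livers.

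**Figure D2:**
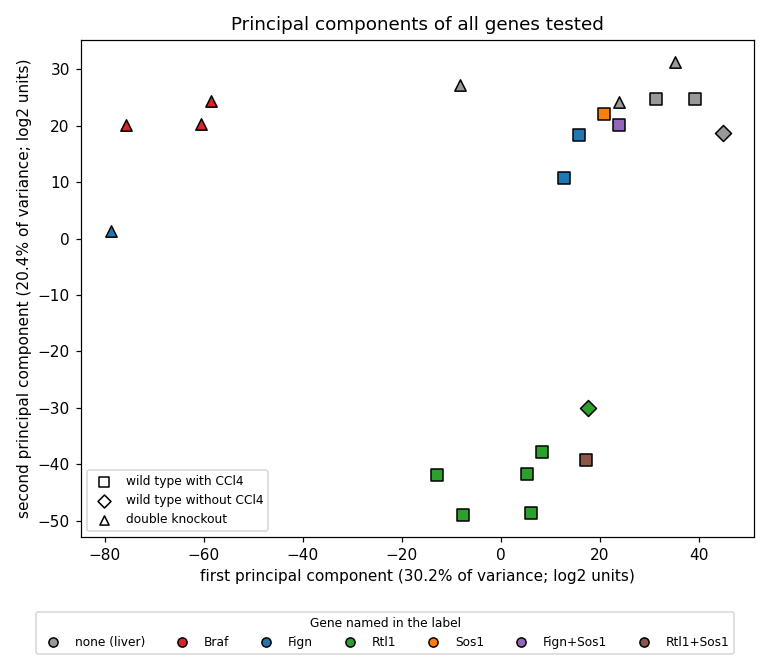
Scores of the 21 arrays on the first (x axis) and second (y axis) principal component of all genes tested, in log2 units; shapes give the mouse line and treatment, colours the gene named in the label. The knockout tumours lie at the left and the Rtl1-marked tumours at the bottom.

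The first comparison asked which genes differed between tumours and livers within mouse lines and treatments. In tumours, 14 of 17 oncofetal and carcinoma markers and 26 of 27 cell cycle genes rose, while 11 of 21 cytochrome P450 and conjugation genes, 11 of 17 bile acid genes and 5 of 16 acute-phase genes fell. With an estimated correlation the oncofetal list kept its call (adjusted p = 0.00226), and the other 4 lists, in this order, did not (adjusted p = 0.184, 0.184, 0.173 and 0.371). The largest rises were those of Afp, the fetal serum protein alpha-fetoprotein (5.43 ± 0.66 log2, SE, 43.2-fold, adjusted p = 0.000164), Bex1 (4.28), the fetal growth factor Igf2 (4.10), the stearoyl-CoA desaturase Scd2 (3.77), Tspan8 (3.71) and Itih5 (3.51). Next came the proteoglycan Gpc3 (3.50), Ly6d (3.46), the activin antagonist Fst (3.34), Cd63 (3.09), Rtl1 (2.97) and Wfdc15b (2.96). Afp exceeded every liver in 14 of 15 tumours, the exception being TB157 (5.68), and Scd2, Ly6d and Fst did so in all 15. The largest falls were those of Cyp2c54 (-4.99 ± 0.93, 31.8-fold, adjusted p = 0.0033), Sult2a8 (-4.66), Cyp2c50 (-4.65), the serum amyloid gene Saa1 (-4.64), Cyp2c38 (-4.16) and Cyp2c29 (-4.14). They were followed by Cyp2c37 (-4.11), Saa2 (-4.05), Ces3b (-3.98), Rgn (-3.97), Hsd17b6 (-3.95) and the hepatic uptake transporter Slco1b2 (-3.91).

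Of 17 measured oncofetal and carcinoma markers, 14 rose and none fell (15 rose when adjusted over the list alone; camera adjusted p = 1.99e-14, and adjusted p = 0.00226 with an estimated correlation). Among them were Golm1 (4.01-fold) and Afp. Of 27 cell cycle genes, 26 rose, such as Aurka (1.21), Racgap1 (1.54), Rrm2 (1.51) and Tpx2 (1.70); all 27 did when adjusted over the list alone (camera adjusted p = 2.74e-22, but adjusted p = 0.184 with an estimated correlation). Knockout liver N31 averaged 6.95 on this list, against 5.40 to 5.87 in the other livers. Of 21 cytochrome P450 and conjugation genes, 11 fell, and 14 did when adjusted over the list alone (camera adjusted p = 4.81e-09, 0.184 as the adjusted p with an estimated correlation). Of 17 bile acid genes, 11 fell, and 14 did when adjusted over the list alone, among them the transporter Slco1a1 (-3.64), the bile acid receptor Nr1h4 (-1.14), Cyp27a1 (-2.11) and the conjugating enzyme Baat (-1.67); camera gave an adjusted p of 3.69e-09, and an adjusted p of 0.173 with an estimated correlation. Of 16 acute-phase genes 5 fell, and 8 did when adjusted over the list alone (camera adjusted p = 8.05e-05; adjusted p = 0.371 with an estimated correlation). Of 16 Kupffer cell and macrophage markers, 4 fell (Cd163 by -1.95, Timd4, Marco and Clec4f), and 5 did when adjusted over the list alone (camera adjusted p = 0.000254; adjusted p = 0.371 with an estimated correlation). In all, 1843 of 19935 genes passed adjusted p 0.05 (988 higher, 855 lower), 570 of them with at least a 2-fold change. Centring each array on its median gave 779 higher and 1038 lower genes, so the share of higher genes depended on the scaling. Leaving out knockout liver N102 or N74 left 1031 and 876 genes, and Rtl1 lost its call with array weights (adjusted p = 0.0529), with an intensity trend and robust variance (0.0505) and with the Xist level of each array as a covariate, added after seeing the data (0.0634).

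Among knockout mice, 4 tumours were compared with 3 livers. The tumours expressed Afp at 13.78 ± 0.03 (SD, n = 4) against 5.63 ± 0.14 in livers (n = 3), a 283-fold difference (8.15 ± 0.61 log2, SE; adjusted p = 8.39e-07). Several imprinted genes rose as well: the zinc finger genes Peg3 (5.80 ± 0.56, adjusted p = 1.18e-05) and Zim1 (4.37), the Notch-related ligand Dlk1 (4.85 ± 0.43, adjusted p = 5.72e-06) and Igf2 (5.01). Further rises were those of Bex1 (7.47), Tspan8 (6.84), Gpc3 (6.73), the intestinal cadherin Cdh17 (5.24), carboxypeptidase E (Cpe, 4.69), Scd2 (4.54) and the microvillus protein villin (Vil1, 4.48). The noncoding RNAs Meg3 (3.11) and Rian (3.52), from the same cluster as Dlk1, also rose (adjusted p = 0.0281 and 0.0239). The falls were led by Saa1 (-5.57), Sult2a8 (-5.41), Saa2 (-5.04), Cyp2c54 (-4.88), Slco1a1 (-4.77), Cyp1a2 (-4.70), the alcohol dehydrogenase Adh4 (-4.64 ± 0.53, adjusted p = 4.63e-05) and paraoxonase Pon1 (-4.63). Cyp7b1 (-4.58), the orosomucoid Orm2 (-4.55), Slc22a30 (-4.55) and Cyp4a12a (-4.55) followed.

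Of 17 oncofetal markers 13 rose (15 adjusted over the list alone; camera adjusted p = 5.3e-14, and adjusted p = 1.72e-05 with an estimated correlation). Of 18 transcriptional outputs of the ERK cascade, 8 rose, such as the feedback inhibitors Spred2 (1.53) and Spry1 (1.07), Epha2 (1.08) and the phosphatase Dusp5 (2.17); 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.47e-05; adjusted p = 0.329 with an estimated correlation). The mean of this list was 7.69 to 7.95 in the 3 Braf-marked tumours, but 6.26 in the Fign-marked T102B, below the 3 livers (6.39 to 6.68). Of 13 genes of the urea cycle and amino acid catabolism, 7 fell, among them the glycine methyltransferase Gnmt (-3.28), Hpd of tyrosine breakdown (-3.18), the proline dehydrogenase Prodh (-3.08) and the urea cycle enzyme Otc (-2.79); 9 fell when adjusted over the list alone (camera adjusted p = 3.63e-06; adjusted p = 0.107 with an estimated correlation). Of 21 cytochrome P450 and conjugation genes 12 fell, and 18 did when adjusted over the list alone (camera adjusted p = 6.98e-09; adjusted p = 0.107 with an estimated correlation). Of 9 markers of biliary and progenitor cells 4 rose: Bicc1 (2.39), Prom1 (2.60), Epcam (1.26) and the keratin Krt19 (1.62). Adjusted over the list alone 5 rose (camera adjusted p = 0.000608; adjusted p = 0.0559 with an estimated correlation). Markers of stellate cells and matrix moved both ways, with Acta2 (2.05), Timp1 (2.85) and Sparc (1.90) higher and the retinol-storing enzyme Lrat (-2.22) lower; 3 of 18 rose and 2 fell, with 5 and 2 when adjusted over the list alone (camera adjusted p = 0.0618). Of 16 Kupffer cell and macrophage markers 2 fell on either adjustment, Cd163 (-1.85) and Marco (-1.74; camera adjusted p = 0.0118; adjusted p = 0.527 with an estimated correlation). No erythroid marker of 4 passed, but their mean was 8.60 in T31 and 7.56 in T74, above the livers (6.10 to 6.35), and 5.38 and 5.52 in the other tumours. Of 10 male-biased liver genes 6 fell (9 adjusted over the list alone; camera adjusted p = 1.03e-05; adjusted p = 0.181 with an estimated correlation), while Xist, the RNA of the inactive X chromosome, was high in 2 of 4 tumours and 1 of 3 livers. In all, 2575 genes passed (1447 higher, 1128 lower). With these 7 arrays alone and the title number as a fixed replicate block, 293 passed (110 higher, 183 lower) and 43 of 80 named genes did not. With only these 7 arrays in the fit 721 passed and 29 of 80 named genes did not, among them Cdh17 (adjusted p = 0.142), Cpe (0.0971), Dusp5 (0.159), Epha2 (0.127), Spry1 (0.0657), Epcam (0.22), Krt19 (0.253), Acta2 (0.0562), Cd163 (0.0705) and Marco (0.219). Leaving out liver N102 or N74 left 1244 and 1037 genes; without T31 and T74, a setting chosen after seeing the data, 2395 passed and 25 of the 80 named genes did not, such as Igf2 (adjusted p = 0.0931), Sult2a8 (0.119) and Cyp2c54 (0.194).

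Among wild type mice given CCl4, 10 tumours were compared with 2 livers. The tumours expressed more Ly6d (4.14 ± 0.77 log2, SE, 17.6-fold, adjusted p = 0.0364), Scd2 (3.31), Afp (3.15, 8.9-fold), Itih5 (3.05) and the interferon-induced Ifi27 (4.0-fold), each above both livers in all 10 tumours. Smaller rises were those of Spats2l (1.56), Dhrs9 (1.53), the tight-junction receptor Cxadr (1.37), the mineralocorticoid receptor Nr3c2 (1.02) and Tbc1d24 (0.83). The tumours expressed less of 2 genes typical of female liver, the sulfotransferase Sult3a1 (-6.01 ± 1.15, 64.2-fold, adjusted p = 0.0422) and A1bg (-4.90). They also expressed less Serpina4-ps1 (-3.82), Sult3a2 (-3.81), Nat8f1 (-2.95), the proton pump subunit Atp6v0d2 (-2.76), the matrix protein dermatopontin (Dpt, -1.85), the stellate cell transcription factor Tcf21 (-1.50), Robo2 (-1.09), Islr (-0.86) and Angptl6 (-0.86). Wrnip1 fell on its brighter probe (-0.92) but not on its other (-0.01). The 2 livers spread widely for A1bg (10.08 ± 3.21, SD) and Sult3a2 (6.77 ± 1.54), which the estimate of the spread shared by all groups does not show. Sult3a1 and Sult3a2 averaged 3.49 and 2.96 in the tumours, below the lower quartile of every array (4.08 or higher), so their folds are not exact.

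Of 17 oncofetal markers 3 rose (Scd2, Ly6d and Afp), and 4 did when adjusted over the list alone (camera adjusted p = 1.29e-08; adjusted p = 0.000374 with an estimated correlation). No interferon-stimulated gene of 21 passed over all genes, but 15 rose when adjusted over the list alone, with Usp18 at 2.62 and Ifit1 at 2.37 (camera adjusted p = 1.69e-14; adjusted p = 0.142 with an estimated correlation). Of 8 female-biased liver genes 2 fell, and 4 did when adjusted over the list alone (camera adjusted p = 1.9e-05; adjusted p = 0.311 with an estimated correlation). No Kupffer cell marker of 16 passed on either adjustment (camera adjusted p = 0.00012, lower in tumours; adjusted p = 0.463 with an estimated correlation). Both livers were Xist-high (9.57 and 9.92), as were 3 of the 10 tumours. In all, 33 genes passed (11 higher, 22 lower), and 9 with the Xist level of each array as a covariate, a setting chosen after seeing the data under which 17 of the 22 named genes did not pass; 11 of the 22, Afp (adjusted p = 0.141) and Sult3a1 (0.0582) among them, did not with only these 12 arrays in the fit. Without liver N150 or N151 the count was 0 (limma) or 6, against 1841 genes at an unadjusted p under 0.05 with both, and without tumour TB157, TA159, TC161 or TD161 it was 53, 15, 15 or 13.

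The difference between the 2 tumour effects was tested as an interaction. The tumour-liver difference was larger in knockout than in wild type CCl4 mice for Peg3 (by 5.17 ± 0.79 log2, SE, adjusted p = 0.00588), Afp (4.99), Dlk1 (4.79), Zim1 (4.26), the phospholipid flippase Atp8a2 (4.06), Steap2 (3.91), Cltrn (3.84) and Vil1 (3.83). A second probe of Steap2 gave -0.06. It was lower for Nat8f5 (-4.16), the carbonic anhydrase Car3 (-4.10), alanine aminotransferase (Gpt, -3.83), Aldh1a7 (-3.73), Gnmt (-3.51), Scp2 (-3.42), the aldehyde oxidase Aox3 (-3.39) and Aldh1a1 (-3.38). The oncofetal list (3 of 17 genes higher, 4 when adjusted over the list alone; camera adjusted p = 1.15e-06) and the biliary and progenitor list (1 of 9, and 3; camera adjusted p = 0.000107) kept their calls with an estimated correlation, at adjusted p = 0.00179 and 0.0243. In all, 146 genes passed (73 larger, 73 lower). This count moved from 8 without wild type liver N151 and 10 without N150 to 397 without knockout liver N31, and was 46 with the Xist level as a covariate added after seeing the data, under which Steap2 (adjusted p = 0.08), Cltrn (0.15), Nat8f5 (0.12), Car3 (0.0511) and Aox3 (0.0566) did not pass; the other arrays that moved it by over 1.5 times were livers N102 (37) and N74 (41) and tumours T31 (231), T74 (83), T102B (362), T148 (94) and TD161 (86).

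Between the livers, 3 knockout and 2 wild type CCl4 samples, 4 genes differed. The phosphodiesterase Gdpd3 was higher in the knockout (4.92 ± 0.48, SE, adjusted p = 0.000109). The class II histocompatibility gene H2-Ea (-3.89), Sult3a2 (-3.81) and the interferon-induced Ifi44l (-1.84) were lower. Of 21 interferon-stimulated genes none passed over all genes and 2 fell when adjusted over the list alone (camera adjusted p = 5.24e-10; adjusted p = 0.265 with an estimated correlation). With only the 5 livers in the fit limma called 0 genes, against 1064 at an unadjusted p under 0.05 in the full fit, and without liver N31 or N150 the count was 7 or 1. Ifi44l did not pass with the Xist level as a covariate, added after seeing the data (adjusted p = 0.0942).

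Between the tumours, 4 knockout tumours were compared with 10 wild type CCl4 tumours. In the knockout tumours 20 of 21 interferon-stimulated genes and all 13 measured urea cycle and amino acid genes were lower than in the others. There 11 of 17 oncofetal markers and 26 of 27 cell cycle genes were higher. With an estimated correlation the first 3 lists kept their calls (adjusted p = 0.0391, 0.0167 and 0.000469), and the cell cycle list did not (adjusted p = 0.189). Gdpd3 (5.86 ± 0.31 log2, SE, adjusted p = 2.49e-09), Afp (5.70), Bex1 (5.37), Peg3 (5.26), Dlk1 (5.04), Gpc3 (5.01), Tspan8 (4.95) and the protease inhibitor A2m (4.50) were the genes with the largest rises by the naming rule. The largest falls were those of Etnppl (-5.72), the steroidogenic enzyme Cyp17a1 (-4.78), Car3 (-4.61), nicotinamide N-methyltransferase (Nnmt, -4.50), H2-Ea (-4.47), the interferon-induced Ifit3 (-4.35 ± 0.48, adjusted p = 6.44e-06), Cyp3a25 (-4.21) and the methionine cycle enzyme Bhmt (-4.21). Further probes of Bhmt gave -4.13 and -1.94. Gdpd3 and H2-Ea differed in the same directions between the livers of these groups, so their differences were not particular to the tumours. Braf was 1.40 higher (adjusted p = 5.12e-05).

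Of 21 interferon-stimulated genes 20 were lower over all genes and over the list alone, such as Rtp4 (-3.14), Xaf1 (-2.09) and Irf7 (-3.49). Camera gave an adjusted p of 2.16e-17, and an adjusted p of 0.0391 with an estimated correlation. This list averaged 5.744 to 6.464 in the knockout tumours and 5.715 to 6.488 in the knockout livers, so these ranges overlapped. It averaged 7.059 to 9.037 in the wild type CCl4 tumours and 6.845 and 6.997 in the livers of that group. All 13 urea cycle and amino acid genes fell, on either adjustment, led by Gnmt (-4.09), Hpd (-3.73), Oat (-3.26) and Prodh (-2.95); the adjusted p was 5.77e-12, and 0.0167 with an estimated correlation. Of 9 gluconeogenesis genes 4 fell (5 adjusted over the list alone), among them the bisphosphatase Fbp1 (-3.10) and Pck1 (-2.18), at an adjusted p of 0.000127, or 0.0483 with an estimated correlation. The 11 oncofetal markers that rose became 12, with 1 falling, when adjusted over the list alone (camera adjusted p = 2.04e-08). Of 27 cell cycle genes 26 rose (27 adjusted over the list alone; camera adjusted p = 8.62e-16; adjusted p = 0.189 with an estimated correlation); the wild type tumour TB161 averaged 7.52 on this list, within the range of the knockout tumours (7.24 to 8.52). Of 18 ERK outputs 9 rose, such as Spry2 (2.57) and Dusp5 (2.15), with 13 when adjusted over the list alone (camera adjusted p = 1.08e-06; adjusted p = 0.189 with an estimated correlation). The mean of this list was 7.69 to 7.95 in the 3 Braf-marked knockout tumours, but in T102B (6.26) it lay within the range of the wild type CCl4 tumours (6.23 to 6.72). Of 9 biliary markers 3 rose, Bicc1 (2.15), Epcam (1.51) and Krt19 (1.93), and 5 did when adjusted over the list alone (camera adjusted p = 0.000756; adjusted p = 0.0391 with an estimated correlation). Of 18 stellate cell and matrix genes 7 rose, led by Timp1 (3.21) and Sparc (2.04), with 9 when adjusted over the list alone (camera adjusted p = 0.000301; adjusted p = 0.356 with an estimated correlation). Markers of blood cells differed too. Of 4 erythroid genes 3 rose on either adjustment, the anion exchanger Slc4a1 (2.28), Rhag (1.62) and Epb42 (0.98; camera adjusted p = 0.0161; adjusted p = 0.357 with an estimated correlation). Their list averaged 8.60 in T31 and 7.56 in T74, but 5.38 and 5.52 in the other knockout tumours and 5.20 to 5.59 in the wild type CCl4 tumours. Of 11 neutrophil genes 2 rose, Cxcr2 (1.11) and Csf3r (0.73), and 1 did when adjusted over the list alone (camera adjusted p = 0.0859); that list averaged 6.87 in T31 and 8.16 in the wild type tumour TB157. In all, 3902 genes passed (2083 higher, 1819 lower), and centring each array on its median gave 1768 higher and 2149 lower genes. Without T31 and T74, a setting chosen after seeing the data, 2714 passed, Rhag (-0.052) and Epb42 (-0.015) turned in sign, and Cxcr2 (adjusted p = 0.447), Csf3r (0.339), Spry2 (0.107), Dusp5 (0.09) and Pck1 (0.0792) did not pass. Genotype, strain, CCl4 and the marking genes differed together between these tumours.

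**Figure D3:**
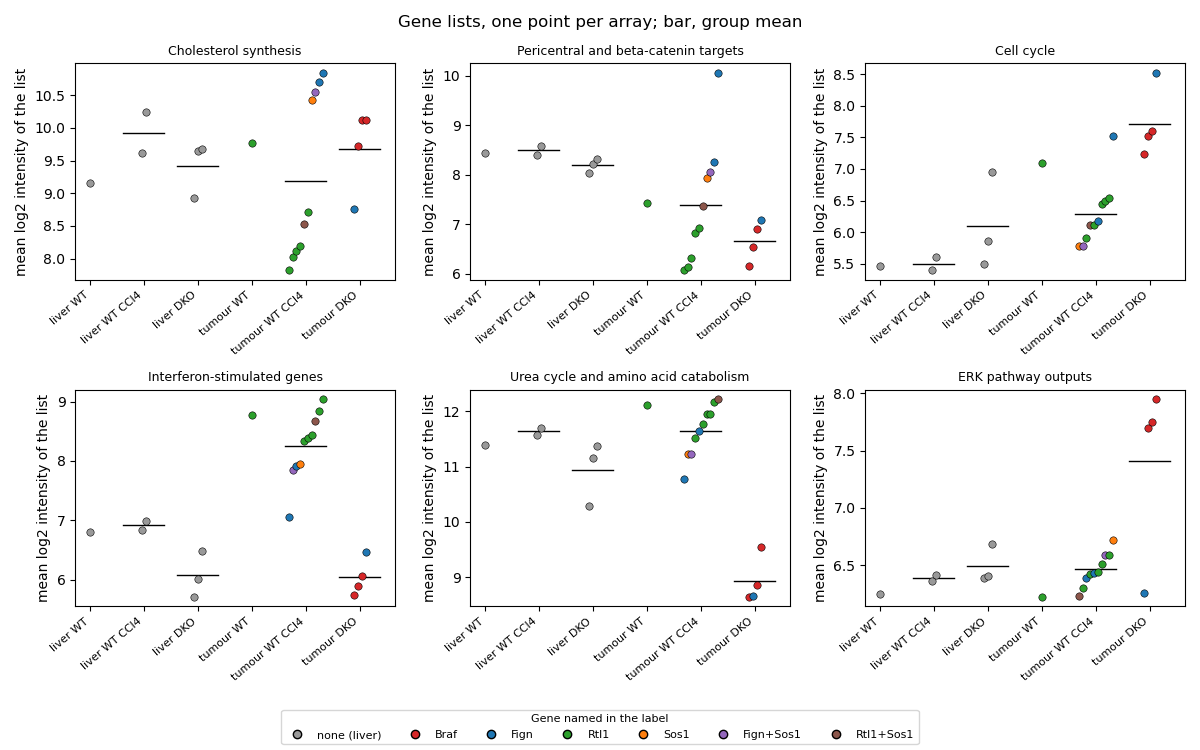
Mean log2 intensity over the measured members of 6 gene lists (y axes) on each array, by group (x axis), coloured by the gene named in the label; bars are group means. The 6 Rtl1-marked wild type CCl4 tumours lie between 7.82 and 8.71 for cholesterol synthesis, and the 4 other tumours of that group between 10.4 and 10.8.

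Within the 10 wild type CCl4 tumours, 6 marked by Rtl1 were compared with the 4 others. In the marked tumours all 15 measured cholesterol synthesis genes and 10 of 16 genes of the pericentral zone of the liver lobule fell, while 8 of 12 p53 targets, 7 of 15 targets of the antioxidant regulator NRF2 and 8 of 21 interferon-stimulated genes rose. With an estimated correlation none of these 5 lists kept its call (adjusted p = 0.0802, 0.35, 0.221, 0.33 and 0.33, in this order). Their largest rises were those of the steroidogenic enzyme Cyp11a1 (5.81 ± 1.27 log2, SE, 56.2-fold, adjusted p = 0.0133), Cplane1 (4.97), the serine protease Htra1 (4.88 ± 0.32, adjusted p = 8.14e-06), Dapl1 (4.75), the kinase Stk33 (4.43), the G protein regulator Rgs2 (4.35), Smim31 (4.22) and the peptide hormone Apela (4.16). All but Cyp11a1, at 5 of 6, were above all 4 other tumours in every marked tumour. The other 2 probes of Cplane1 gave 0.50 and 0.44. The largest falls were those of Cyp2c50 (-5.47 ± 0.62, adjusted p = 0.000294), Cyp2b9 (-5.27), Cyp2c37 (-4.97), Rgn (-4.94), Slco1b2 (-4.92), Sult2a8 (-4.65), Cyp2e1 (-4.62) and Cyp3a16 (-4.61). Rtl1 itself was 4.12 higher. Of its imprinted neighbours, Dlk1 (-0.29, adjusted p = 0.536), Meg3 (-2.13, 0.0624), Rian (-1.70, 0.228), Dio3 (-0.27, 0.312) and Begain (-0.24, 0.417) did not pass.

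All 15 measured cholesterol synthesis genes fell, over all genes and over the list alone, among them Fdft1 (-2.69 ± 0.13), Nsdhl (-3.19), Cyp51 (-3.52) and Hmgcs1 (-3.00); the camera adjusted p was 4.45e-24, and 0.0802 as the adjusted p with an estimated correlation. Of 16 pericentral and beta-catenin target genes 10 fell, among them glutamine synthetase (Glul, -3.47), Cyp1a2 (-4.40), Rnf43 (-1.56) and the glutamate transporter Slc1a2 (-3.18); 15 fell when adjusted over the list alone (camera adjusted p = 4.34e-08; adjusted p = 0.35 with an estimated correlation). Of 16 lipogenesis genes 8 fell, such as fatty acid synthase (Fasn, -1.92) and the desaturase Fads1 (-2.08), with 13 falling and 1 rising when adjusted over the list alone (camera adjusted p = 9.92e-06; adjusted p = 0.309 with an estimated correlation). Of 12 p53 targets 8 rose on either adjustment, such as Trp53inp1 (1.41), Ccng1 (0.84), Mdm2 (0.72) and Phlda3 (1.16); camera gave an adjusted p of 5.58e-06, and an adjusted p of 0.221 with an estimated correlation. Of 15 NRF2 targets 7 rose, such as the sulfiredoxin Srxn1 (2.22) and the cystine transporter Slc7a11 (4.01), and Osgin1 fell (-1.46); 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.42e-05; adjusted p = 0.33 with an estimated correlation). Of 21 interferon-stimulated genes 8 rose, among them Rsad2 (2.82), Oasl1 (2.53) and Mx1 (2.06), and 11 did when adjusted over the list alone (camera adjusted p = 7.17e-07; adjusted p = 0.33 with an estimated correlation). Of 8 female-biased genes 5 fell, such as Cyp2b13 (-4.50), with 5 falling and 1 rising when adjusted over the list alone (camera adjusted p = 8.3e-06; adjusted p = 0.221 with an estimated correlation); Xist was high in 1 of the 6 marked and 2 of the 4 other tumours. No cell cycle gene of 27 passed over all genes or over the list alone (camera adjusted p = 0.96). In all, 2165 genes passed (1309 higher, 856 lower), and 1355 without tumour TE161. With the title number as a fixed replicate block, a setting chosen after seeing the data, 948 passed.

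Within the same 10 tumours, 3 marked by Fign were compared with the 7 others. The marked tumours expressed more of the aquaglyceroporin Aqp3 (3.52 ± 0.28 log2, SE, adjusted p = 0.00081), the phosphate transporter Slc34a2 (3.45), Fign itself (3.42), Tenm3 (3.21), the phosphatase Dusp14 (3.01), the complement receptor Cr2 (3.00), the noncoding RNA Meg3 (2.91, adjusted p = 0.031) and Greb1 (2.31). They expressed less of the carbonyl reductase Cbr3 (-3.49), Wfdc15b (-3.26), BC040756 (-2.43), the glyoxylate aminotransferase Agxt (-2.17), the glucuronosyltransferases Ugt2b37 (-1.88) and Ugt2b35 (-1.76), the interferon-induced Mx2 (-1.57) and Slc44a3 (-1.53). Of 13 clock genes 3 rose, Per3 (0.90), Bhlhe41 (1.08) and Tef (0.72), with 7 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.000536; adjusted p = 0.287 with an estimated correlation). Of 16 pericentral genes 1 rose over all genes (Tnfrsf19, 1.41) and 14 when adjusted over the list alone (camera adjusted p = 4.61e-12; adjusted p = 0.291 with an estimated correlation). No cholesterol synthesis gene passed over all genes, but all 15 rose when adjusted over the list alone (camera adjusted p = 4.79e-17; adjusted p = 0.291 with an estimated correlation). No neutrophil marker of 11 passed on either adjustment (camera adjusted p = 0.00233; adjusted p = 0.546 with an estimated correlation), and the list averaged 8.16 in the Fign-marked TB157 against 4.60 to 5.27 in the other 9 tumours. The pericentral and cholesterol lists are not independent of the Rtl1 comparison, since 6 of the 7 other tumours carried the Rtl1 mark. In all, 56 genes passed (36 higher, 20 lower), from 5 without TB157 to 1517 without TB159, the tumour marked by Sos1 alone, and 953 with array weights (398 higher, 555 lower); leaving out any of the 10 tumours moved the count by over 1.5 times. With the Xist level as a covariate, added after seeing the data, 34 passed, and Meg3, Slc34a2, Wfdc15b, Agxt, Ugt2b37, Slc44a3 and Tnfrsf19 did not.

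The 3 tumours marked by Sos1 did not differ from the 7 others in any gene at adjusted p 0.05 (limma; 0 genes, against 1475 at an unadjusted p under 0.05, the smallest adjusted p being 0.672). Of the 3, TE161 also carried the Fign and TD161 the Rtl1 mark. Without TD161 the count was 19.

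The remaining pair, 1 wild type tumour and 1 liver without CCl4, has no replicates, and its values describe these arrays only. The tumour was marked by Rtl1, which stood at 11.27 against 5.21 in the liver. Afp (3.72), Scd2 (2.67) and Igf2 (1.89) were higher in the tumour by these log2 differences, and Glul (-2.23) and Cyp2e1 (-1.80) were lower. Compared with 10000 random lists of the same size and expression, the median difference of 9 lists lay at percentile 100, namely cell cycle (1.87), oncofetal (1.70), interferon-stimulated (1.64), immediate early (0.71), urea cycle and amino acid (0.68), T and NK cell (0.59), cholesterol synthesis (0.55), NRF2 (0.55) and stellate cell and matrix genes (0.37). The male-biased (-1.77), cytochrome P450 (-1.28), bile acid (-1.13), pericentral (-0.94) and Kupffer cell (-0.45) lists lay at percentile 0. The random lists drew their genes independently, so lists whose genes move together reach such percentiles easily. These percentiles are therefore not tests of the lists.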

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

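The test of the cholesterol genes against livers was set after its result was seen, and the Xist covariate and the subsets by Rtl1 mark were chosen after seeing the data, before their own results were seen. Of 90 tests for an array far from the rest of its group (genes of the insertion sites and the Dlk1-Dio3 cluster, the targeted genes and the mean of each list, in the 4 knockout and the 10 wild type CCl4 tumours), 6 found one, where chance gives about 1 in 20. Among knockout tumours, Dio3 stood at 8.24 in the Fign-marked tumour T102B and at 4.27 to 4.76 in the 3 Braf-marked ones. The ERK output list averaged 6.26 in T102B and 7.69 to 7.95 in the Braf-marked tumours, 1 of which shares its title number, against 6.39 to 6.68 in the knockout livers and 6.23 to 6.72 in the wild type CCl4 tumours. The p53 target list averaged 8.03 in the Braf-marked tumour that shares the title number of T102B and 7.64 to 7.69 in the others. Among wild type CCl4 tumours, the Fign-marked TB161 had a cell cycle mean of 7.52 (others 5.78 to 6.53) and a periportal mean of 8.33 (others 11.02 to 11.87). The neutrophil list averaged 8.16 in the Fign-marked TB157 and 4.60 to 5.27 in the others.

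The tumour effect differed between knockout and wild type CCl4 mice, by the interaction test, for 16 genes of the naming rule. The differences were 5.17 for Peg3, 4.99 for Afp, 4.79 for Dlk1, 4.26 for Zim1, 4.06 for Atp8a2, 3.91 for Steap2, 3.84 for Cltrn and 3.83 for Vil1. On the other side were Nat8f5 (-4.16), Car3 (-4.10), Gpt (-3.83), Aldh1a7 (-3.73), Gnmt (-3.51), Scp2 (-3.42), Aox3 (-3.39) and Aldh1a1 (-3.38). With the Xist level as a covariate 5 of the 16, Steap2, Cltrn, Nat8f5, Car3 and Aox3, did not pass (adjusted p = 0.0511 to 0.15). The oncofetal list (adjusted p = 0.00179 with an estimated correlation) and the biliary list (0.0243) differed as well. Outside the named genes, 386 of 7057 probes without a single gene symbol were higher in knockout tumours than in livers and 162 were lower.

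The lower cholesterol synthesis genes of the Rtl1-marked wild type CCl4 tumours are a pattern a technical or animal difference might produce. With the Xist level as a covariate the median difference over the 15 genes was -2.24, against -2.23 without it, and all 15 stayed past the threshold, which argues against sex as the whole source. The difference also stood between tumours that share a title number, with medians of -2.12 among TA161 to TE161 and -2.14 between TA159 and TB159, which argues against a difference between animals if these numbers mark animals. The marked tumours lay below the livers of their own group (median -1.79; array means 7.82 to 8.71 against 9.61 to 10.2), so a rise in the other tumours (0.706 above the livers) is not the whole of it. An effect linked to the Rtl1 mark stays open as a hypothesis, but the marked tumour without CCl4 averaged 9.77 against 9.16 in liver N120, and the Fign-marked knockout tumour T102B averaged 8.77, so the mark and low values did not always go together, and CCl4 is untested.

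The second pattern is the low count of genes in the wild type CCl4 comparison (33) beside that in the knockout comparison (2575). With 2 of the 3 knockout livers at least 1037 genes were called, which argues against the number of livers as the whole cause. With the Xist level as a covariate the wild type count was 9, below the bound set beforehand for excluding sex, but that bound was wrong for this design: both livers and only 3 of 10 tumours were Xist-high, so the covariate overlaps with the contrast and sex cannot be told apart from it. The 6 Rtl1-marked tumours alone against the same 2 livers gave 1047 genes, and the 4 others 12. Both fits gave the marked and the other tumours separate means, so they share an estimate of the spread. The gap between 1047 and 12 therefore does not come from the spread. How far the spread between differently marked tumours lowers the pooled count is not settled by these fits. A larger difference from liver in the Rtl1-marked tumours would give these counts and stays open, and the sets also differ in size. They differ in Xist as well: among the marked tumours only TA159 was Xist-high (9.93), among the others TB157 (9.92) and TB159 (9.23). Sex therefore cannot be told apart from this gap either.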

How the results depend on the processing

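The Xist covariate, the subsets by Rtl1 mark, the fits without T31 and T74 and the fixed block in the Rtl1 comparison were chosen after seeing the data, and the other alternatives before. Across 9269 values of 412 named and called gene results under the alternatives, 8134 kept direction and call, 1133 lost the call and 2 reversed; 200 results lost it at least once. The 2 were Rhag (-0.05212) and Epb42 (-0.01506) between tumours without T31 and T74, the knockout tumours with high erythroid markers. The counts without both were 2395 in the knockout (1709 shared with the 2575) and 2714 in the between-tumour comparison (2257 shared with the 3902). In the wild type CCl4 comparison all 22 lost it when some array was left out, and 17 with the Xist covariate, where the adjusted p of Afp became 0.197 and of Sult3a1 0.197. Of 135 list calls 10 held with an estimated correlation: the oncofetal list in 5 comparisons (both tumour-liver comparisons by mouse line, the one over all groups, the interaction and the one between tumours), the biliary list in the last 2 of these, and the interferon, urea cycle and gluconeogenesis lists between tumours. The other 125 calls were lost with it. With the preset correlation, 13 calls were lost and 5 gained when dim genes were left out. Under the random block 3 were lost and 2 gained, and 0 lists reversed. The number of arrays limits all of these, and the arrays' background levels were not analysed here. A cause was not tested unless fewer samples or genes explain a change.

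The tumour-liver count over all groups was 570 with a 2-fold threshold, by construction. The dim-gene filter gave 21 genes in the wild type CCl4 comparison, array weights 953 in the Fign comparison (56 without), and fits with only the compared arrays, which hold fewer samples, gave 721 in the knockout and 0 in the liver comparison; the cause was not tested. The Xist covariate gave 9 genes in the wild type CCl4 comparison, 46 in the interaction and 34 in the Fign comparison. The 6 Rtl1-marked tumours alone gave 1047 genes against the wild type CCl4 livers, the 4 others 12. For Fign within the wild type CCl4 tumours, the difference in medians was 3.685 with an adjusted p of 0.05.

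Some tumours and livers share title numbers, not said by the labels to mark animals. Xist was alike on all arrays of each shared number, a hint from the data. Deviations from group means correlated at 0.01 to 0.16 in same-numbered knockout tumours and livers, and at -0.12 to 0.05 otherwise. Within a group they lean negative by construction, so those cannot speak against shared animals. Estimated block correlations (-0.09 knockout, -0.034 Rtl1) do not settle it. As a fixed replicate block the number gave 293 genes in the knockout comparison (110 higher, 183 lower, 272 shared with the 2575). That fit held only these arrays, which without the block gave 721 and lost 29 of 80 named genes. In the Rtl1 comparison the fixed block gave 948 (888 shared with the 2165). In the knockout comparison 43 of 80 named genes then did not pass, among them Igf2 (adjusted p = 0.0502), Saa1 (0.0554), Orm2 (0.0554), Cyp4a12a (0.0576), Cyp7b1 (0.0862), Cpe (0.137), Cdh17 (0.208), Epcam (0.33), Krt19 (0.343), Prom1 (0.067), Acta2 (0.0673), Timp1 (0.0791), Sparc (0.0523), Spry1 (0.077), Dusp5 (0.212) and Epha2 (0.194). In the Rtl1 comparison 18 of 94 did not, among them Cyp11a1 (0.125), Cyp2e1 (0.0952), Cyp3a16 (0.0956), Mdm2 (0.0794) and Phlda3 (0.0531). These fits have fewer residual degrees of freedom, so a lost call does not by itself show a smaller difference. As a random replicate block the title number moved no count by over 1.5 times, with 2283 and 2100 genes in these comparisons, 1702 over all groups, 44 in the wild type CCl4 and 4506 in the between-tumour comparison. The block correlations used were negative, so these counts cannot show what shared animals would do. Averaging same-numbered tumours gave 2146 genes over all groups (1585 shared with the 1843) and 32 in the wild type CCl4 comparison (16 shared with the 33). There 13 of 22 named genes did not pass, among them Afp (adjusted p = 0.0917), Sult3a1 (0.0603), Ly6d (0.067), A1bg (0.099), Ifi27 (0.104) and Itih5 (0.0508).

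Leaving out each array in turn, counts ranged from 876 (without knockout liver N74; 1031 without N102) to 1970 (without TB159) over all groups, and from 1037 (without liver N74; 1244 without N102) to 3521 (without liver N31) for knockout mice. For wild type CCl4 mice they ranged from 0 (without liver N150; 6 without N151, where the lone liver is assumed to vary like the other groups) to 53 (without TB157). The interaction ranged from 8 (without wild type liver N151; 10 without N150) to 397 (without knockout liver N31). The liver comparison ranged from 1 (without N150) to 7 (without N31), the between-tumour comparison from 2903 to 3967, and the Rtl1 comparison from 1355 (without TE161) to 2180. The Fign comparison ranged from 5 (without TB157) to 1517 (without TB159, which leaves Fign-marked against Rtl1-marked tumours), with 21, 154, 19, 24, 20, 23, 17 and 18 without TB161, TE161, T148, T160, TA159, TA161, TC161 and TD161. The Sos1 comparison ranged from 0 to 19 (without TD161). The insertion-gene differences ranged from 1.506 to 1.77 for Braf, 3.373 to 4.096 for Fign, 4.161 to 4.41 for Rtl1 and 1.117 to 2.335 for Sos1 over all tumours. Within the wild type CCl4 tumours they ranged from 2.971 to 3.996 for Fign, 3.991 to 4.29 for Rtl1 and 0.9431 to 2.161 for Sos1. The Sos1 call over all tumours was lost without TE161 or without TB159 (adjusted p = 0.0769 in each exact permutation test), and fell to 0.0278 within the wild type tumours without TD161.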

Other observations

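The genes and arrays of the first 2 paragraphs were singled out after their values were seen. The hypothesis on imprinted genes was formed after seeing the data but tested on genes set aside as not yet seen. Joining the splits drawn for the Fign and Sos1 comparisons was decided after both counts were seen.

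Igf2, the fetal growth factor, differed between tumours beyond what the comparisons describe. It stood at 13.17 to 13.52 in the 4 knockout tumours, at 13.31, 13.21 and 11.39 in the 3 Fign-marked wild type tumours TB157, TB161 and TE161, and at 11.92 in the Rtl1-marked TA159. The other wild type tumours lay between 6.36 and 9.90. Glul, a pericentral enzyme, reached 13.3 in TB161, above the livers (10.33 to 12.12), and lay between 7.24 and 9.16 in the 6 Rtl1-marked wild type CCl4 tumours.

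Knockout liver N31 had a cell cycle mean of 6.95, against 5.40 to 5.87 in the other livers, while its Afp was 5.47, within the range of the livers.

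Because several imprinted genes rose in the knockout tumours, a hypothesis was that imprinted genes as a group were higher there. On 32 measured imprinted genes set aside as not seen before, 2 rose, 4 fell and the median difference was -0.106. Dcn, among those that fell, was also a member of the stellate cell and matrix list, so its value was not new. Camera with an estimated correlation gave p = 0.914, so these 32 genes did not rise as a group, and the hypothesis was not borne out on them. The set left out the imprinted genes already seen to rise, which leans the test against a rise. It therefore does not speak for all imprinted genes.

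Whether other splits of the same arrays into groups of the same sizes call as many genes was also counted. For the overall tumour-liver comparison 1 of 100 splits, the real one, called 1843 genes, and the highest other called 257. For the knockout comparison 1 of 35 splits called 2575, the highest other 1305; that split set tumour T31 with the 3 livers against the other 3 tumours. For the tumours of both lines 1 of 100 splits called 3902, the highest other 1362, which exchanged T102B for TA161. In the Rtl1 comparison 1 of 100 splits called 2165, the highest other 7. For these 4 counts chance can be excluded at the 5% level only if single arrays can be exchanged freely. The splits ignored shared title numbers and, in the overall comparison, mouse line and CCl4 status. If the numbers mark animals, these splits cannot decide whether chance gave the counts. The Fign and Sos1 comparisons both split the same 10 tumours 3 against 7, and the splits drawn for them covered 119 of the 120 possible. Of these 119, 4 (3.36%) called at least the 56 genes of the Fign comparison. That share does not tie the count to the Fign mark, since most of the other tumours carried the Rtl1 mark and other splits called more. The highest other called 485, several times the real count. It set TB157, TE161 and TB159, none of them Rtl1-marked, against the rest. The next called 111, with TB159 in place of TB157 beside the Fign-marked TB161 and TE161. A split with T148, TA159 and TA161, all Rtl1-marked, called 72. TB157, TB161 and TB159, none of them Rtl1-marked, called 1, so setting tumours without that mark apart did not always call many genes. The Sos1 comparison called 0 genes, so all 100 of its splits reached that count by construction and say nothing about chance; the highest other was the same split, with 485.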
